A study of Homo sapiens with 8 samples.

How the data were processed

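Acetylation of histone H3 at lysine 9 (H3K9ac) and of histone H4 at lysine 16 (H4K16ac) was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in KGN cells. KGN is an established human ovarian granulosa tumour cell line. Per the labels' protocols, the cells were grown with or without 1 mM butyrate, a short-chain fatty acid that inhibits histone deacetylases, for 6 h. The series has 8 samples, 4 from each condition, with 1 library each for H3K9ac, H4K16ac, a nonspecific immunoglobulin (IgG) and input chromatin. Peak lists of 6 libraries were analysed. The 2 input samples were not analysed here.

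Per the submitters' processing notes, the tools included CASAVA 1.7 and MACS2 2.1.0, and the genome build was hg19 (GRCh37). The aligner, the duplicate filter and the annotation release are not given in the sources used here. Each list is 1 library's MACS2 narrow peak call with several summits per peak, per the names and columns of the deposited files, and the authors added Ensembl gene annotation to every row. PeakFoldEnrichment is the authors' fold, a ratio of summit pileup to local background. The p and q columns are the deposited −log10 values of MACS2. The deposited score is 10 times −log10 q in the H3K9ac and IgG lists and 10 times −log10 p in the H4K16ac lists. The largest q in the H3K9ac lists the authors deposited was 0.0500 in control and 0.0499 with butyrate, so these lists hold peaks up to a q of 0.05. The H4K16ac lists were limited on p instead. Their largest p was 0.00500 in control and 0.00499 with butyrate, and their largest q was 0.304 and 0.621. Fold, p and q are the authors' own values for each peak and were used here to describe, rank and filter peaks, to compare the limits of the lists, and to recover pileup, background and depth.

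The positions in the lists were compared with a RefSeq gene table of GRCh38.p14. Gene starts in the authors' columns lay a median of 66 bp from the RefSeq starts of the same genes, and 98.5% of 15780 genes lay within 100 kb. Coordinates are therefore given as deposited and read as GRCh38, although the processing notes name hg19. The narrowest peak of each histone list, end minus start, had exactly the fragment length recovered from the values of that list (232, 251, 252 and 236 bp). Starts were therefore taken as counted from 0 and are printed with 1 added. The peak names in both lists of the samples labelled H4K16ac carry the letters k12 in place of a lysine 16. Whether these libraries used another antibody than the label says cannot be told from the files, and H4K16ac below means the libraries so labelled.

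Rows that shared bases were merged to 1 peak, and chromosomes 1 to 22 and X were kept. Peaks were called shared between lists when they overlapped by at least 1 bp. A peak present with butyrate alone is called gained, and a peak present in control alone is called lost. Chance overlap was taken from 100 random placements, in which the peaks of 1 list were shifted together along each chromosome (10 placements for the location of peaks). A gene had a promoter peak when a peak reached within 1 kb of its start, either the authors' start or the RefSeq start on the same strand. The gene table gives no strand, so strands came from the authors' annotation columns. Of 19974 protein-coding genes, 15780 had a strand and start, and 3459 more had no histone peak near either end and count as having none. The remaining 735 genes were left out, which leaves 19239. Peaks outside promoters were assigned to gene bodies where they overlapped 1 of these 19239 genes and to intergenic sequence elsewhere. Peaks at the 735 genes left out thus count as intergenic unless they overlap another gene. This lowers the promoter and gene body shares by an amount that was not computed. Exact (Clopper-Pearson) 95% intervals cover counting of peaks or genes only.

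There is 1 library per condition and antibody, so no difference between conditions was tested and no p-value is given. Before the data were examined, 12 pathway lists and 6 lists of cell type markers were fixed. A list's count is set beside 10000 random lists of the same size, matched on gene length and on the presence of 1 or 2 start sites. A second set of random lists, added after seeing the data, was drawn in the same way from genes without a control peak (gained H3K9ac) or with one (lost H4K16ac). The percentiles describe these libraries only. Genes named in the text follow a rule fixed at the same time. It takes 15 anchor genes and, per mark and direction, the 5 genes with the highest −log10 q at a promoter peak of 1 condition with no peak of the other in the gene or within 10 kb. It further takes up to 3 changed members per list and the 5 strongest promoter peaks per library. Where 4 or 5 members of a list changed, the further members are named too, so that AMHR2, INHBA, LPL, INSL3, SNAP25, RBFOX3, ACADM, IL1A, BSG, FDXR and SCARB1 were named after their values were seen. Some genes that the rule takes are not reported here. CYB5A, NDUFV1, TCF21 and NKG7 were list members without a usable start.

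Sequencing depth is not in the lists. MACS2 derives fold and p from 2 numbers, the pileup at the summit and the local background, so both were solved for at each summit. At least 99.9977% of summits in each list gave whole-read pileups with a p within 0.001 of the deposited value on the −log10 scale, after a scale of 0.897 for the butyrate H4K16ac list. The lowest background is the genome-wide mean. With an assumed genome of 2700000000 bp it implies 24.3 and 29.4 M H3K9ac reads in control and butyrate, and 17.4 and 23.9 M H4K16ac reads. Ratios between libraries do not depend on the assumed genome. The implied background reads were 29.2, 30.4, 21.7 and 21.4 M for the same lists. The H3K9ac lists were thus called against 1.34 and 1.42 times as many background reads as the H4K16ac lists, so the marks' peak numbers differ in threshold and in background and are compared between conditions only within a mark.

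Alternatives chosen before the data were examined were a −log10 q of at least 5, a fold of at least 5, equal numbers of top peaks, merging within 1 kb, removal of peaks that overlap IgG peaks, overlap by 50% of the shorter peak, a promoter window of 2.5 kb, and the authors' own closest-gene columns. A q of at most 0.05 in every list, a thinning of the butyrate H3K9ac reads to the control number and the second set of random lists were added after seeing the data. The thinning drew each summit's reads binomially 20 times and can lose peaks but not add new ones.

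Code was tested on simulated data. Overlap calls for 2172 intervals gave 0 differences from bedtools 2.31.1. All 200 genes given a simulated peak were recovered among 19239 genes. Of 200 random lists of 25 genes tested on gained H3K9ac, 3.5% fell outside the middle 95% of the random distribution. Pileups were recovered for 100% of 4862 simulated summits. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.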

Results

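The data are peak lists from KGN cells, a human granulosa tumour line used as a model of the hormone-producing cells that surround the oocyte. Cells without treatment were set beside cells given 1 mM butyrate for 6 h, and the question was how butyrate changes the genome-wide pattern of 2 histone acetylation marks. H3K9ac lies mainly at the promoters of active genes. H4K16ac is deposited mainly by the acetyltransferase KAT8 and goes with open, transcribed chromatin. Each mark was read in 1 library per condition, with no replicates, so all differences below are differences between 2 libraries. The implied sequencing depth was 24.3 M reads (M, 1000000 reads) for control H3K9ac, 29.4 M for butyrate H3K9ac, 17.4 M for control H4K16ac and 23.9 M for butyrate H4K16ac.

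With butyrate, H3K9ac peaks appeared at many sites that had none in control. Among the genes that gained a promoter peak were FST, the activin-binding protein follistatin, WNT4, a signalling ligand of ovarian development, and IL1B, the cytokine interleukin-1 beta. The list held 22215 peaks in control and 79356 with butyrate, 3.57 times as many. These peaks covered 20.3 Mb and 59.8 Mb. Of the control peaks, 92.4% (95% interval 92.0 to 92.7) overlapped a butyrate peak, against 4.92% under random placement. As deposited, 1698 control peaks were lost and 61089 butyrate peaks were gained. With equal numbers of top peaks from the 2 lists, 79.7% of control peaks were shared and 7743 were gained, so both counts rest largely on the lengths of the lists.

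**Figure D1:**
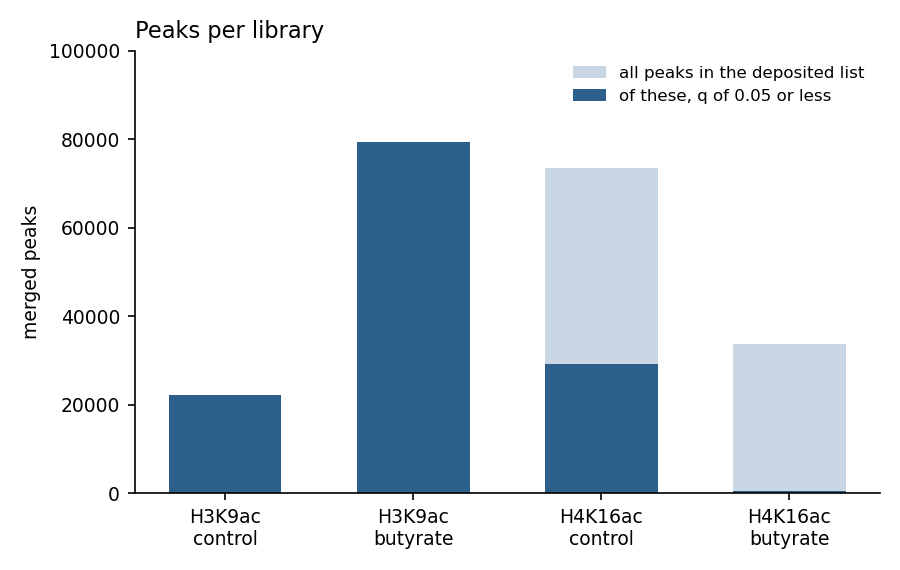
Merged peaks per library, with the part at a q of 0.05 or less in dark blue and 1 library per bar. H3K9ac had 22215 peaks in control and 79356 with butyrate, and H4K16ac had 73586 and 33752, of which 29141 and 381 had a q of 0.05 or less.

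The gained H3K9ac peaks were narrow and mostly lay away from promoters. Their median width was 404 bp, against 1279 bp for butyrate peaks that overlapped a control peak. Promoters held 68.6% of these shared peaks but 7.72% (7.51 to 7.93) of the gained ones. Gene bodies held 56.2% of the gained peaks and intergenic sequence 36.1%, where random placement of the butyrate list put 2.15% at promoters and 41.7% in gene bodies. Over all peaks, the promoter share went from 61.5% (60.8 to 62.1) in control to 21.7% with butyrate, a drop that depends on list length, since with equal numbers of top peaks the butyrate share was 54.5%. Within the butyrate list the gained peaks had a median fold of 3.22, against 5.39 for the shared peaks. At a fold of at least 5 in both lists, the number of butyrate peaks was 1.24 times the control number, and at a −log10 q of at least 5 it was 1.87 times.

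**Figure D2:**
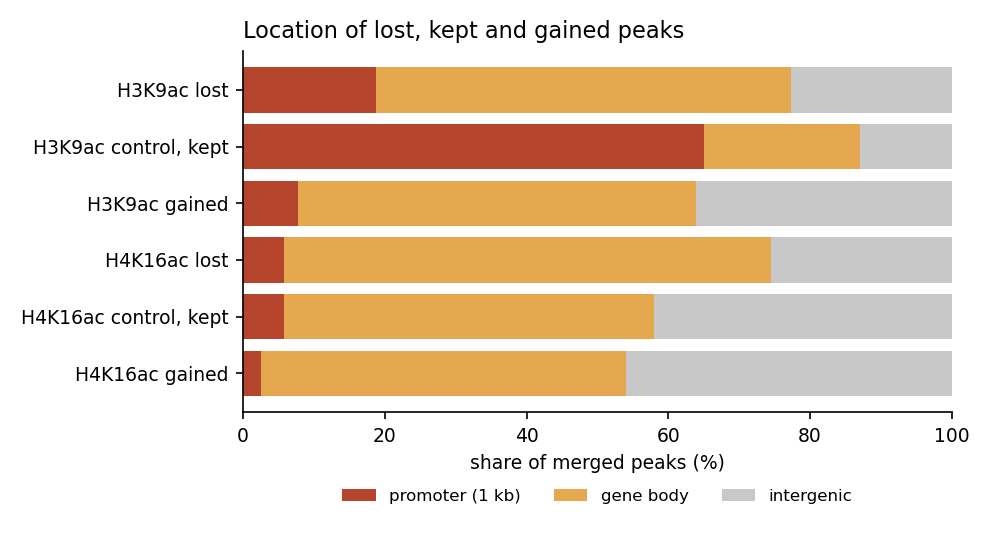
Share of merged peaks (%) at promoters (within 1 kb of a gene start), in gene bodies and in intergenic sequence, for peaks lost, kept and gained with butyrate. Kept H3K9ac control peaks were at promoters in 65.0% of cases and gained H3K9ac peaks in 7.72%, while H4K16ac peaks in each class lay mainly in gene bodies.

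At the level of genes, H3K9ac promoter peaks were found at 10617 of 19239 protein-coding genes in control and at 12348 with butyrate. The mark was kept at 10583 genes, gained at 1765 and lost at 34. A gene counts as kept when both lists have a promoter peak, which need not be an overlapping one. The gained genes were 20.5% of the 8622 genes without a control peak. These include the 3459 genes with no histone peak near either end, which cannot gain one and so lower the share. With equal numbers of top peaks from the 2 lists the counts came to 626 gained and 510 lost, and with the authors' own closest-gene columns to 2207 and 888. At a fold of at least 5 in both lists, 1585 genes gained and 1259 lost a promoter peak, and at a −log10 q of at least 5 it was 1453 and 190. The small number of lost genes thus depends on the lengths of the lists, on the limit of peak strength and on how peaks are tied to genes.

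Genes of the granulosa cell itself were among those that gained H3K9ac. In the granulosa identity list, 11 of 23 genes had a promoter peak in control and 16 with butyrate. The 5 gained genes were FST, WNT4, BMPR1B, a BMP receptor, AMHR2, the receptor for anti-Müllerian hormone, and INHBA, an activin subunit. This gain was at the 96.3 percentile of matched random lists, and at 92.4 among random lists of genes without a control peak, a comparison chosen after seeing the data. Below, the second percentile in parentheses is from that comparison. Of 27 steroidogenesis genes, 12 had a peak in control and 14 with butyrate, the additions being HSD17B1 and AKR1C3, both hydroxysteroid dehydrogenases (percentiles 44.4 and 25.7). With a 2.5 kb promoter window this list gained 0 genes, since both had a control peak within 2.5 kb. In the list of PPAR signalling and fatty acid metabolism, 19 of 30 genes had a peak in control and 23 with butyrate. The 4 gained genes were PPARGC1A, ANGPTL4, FABP3 and LPL (percentiles 77.9 and 86.3). PPARGC1A is a transcriptional coactivator of mitochondrial and fatty acid genes, and FABP3 a fatty acid carrier. ANGPTL4 inhibits LPL, which is lipoprotein lipase. The butyrate peak at LPL had a MACS2 −log10 p of 3.36, below the lowest value of 3.46 in the control list. An equally strong control peak would not have been listed, so this gain can rest on the looser limit alone. Among 26 inflammatory genes, 15 and 18 had a peak, with IL1B, IL1A and ICAM1 gained (percentiles 60.3 and 74.8). PPARGC1A and AMHR2 had a control peak within 2.5 kb as well.

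Several other lists were nearly full in control. All 43 ribosomal protein genes, all 27 respiratory chain genes and all 23 genes of histone acetyltransferases and readers had an H3K9ac promoter peak in both conditions. So did 24 of 25 cell cycle genes. Of 22 deacetylases and sirtuins, 21 had a peak in control, and HDAC9 was added with butyrate. The apoptosis list went from 22 to 23 of 24 genes with BCL2, a survival factor. The cholesterol list went from 21 to 22 of 25 with LIPE. Butyrate transport and receptors, a list with room to gain, went from 7 to 8 of 14 with SLC16A7, a monocarboxylate transporter.

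Of the 54 markers of other cell types without a control peak, 14 gained H3K9ac (25.9%), against 18 of 64 such members of the pathway lists (28.1%) and 20.5% of all such genes. The last share is lowered by the 3459 genes with no histone peak near either end. How many list members are genes of this kind was not counted. Theca and ovarian stroma markers went from 3 to 7 of 9, with LUM, COL1A1, COL1A2 and INSL3 gained, which is 4 of the 6 without a control peak (percentiles 99.7 and 98.99). Neuron markers went from 3 to 8 of 15, with SLC17A7, PAX6, NEUROD2, SNAP25 and RBFOX3 gained, 5 of the 12 without a control peak (percentiles 99.2 and 87.3). COL1A1 and SLC17A7 had a control peak within 2.5 kb. Blood and immune markers went from 0 to 2 of 12 (CSF1R and LCK), endothelial markers from 0 to 2 of 8 (ERG and CLDN5) and epithelial markers from 2 to 3 of 10 (CLDN4). Oocyte markers stayed at 2 of 10. The gains rested partly on weaker peaks. With equal numbers of top peaks, granulosa identity gained 3 genes, the PPAR list 2, the inflammatory and steroidogenesis lists 1 each, neuron markers 2 and blood and immune markers 1. The theca and stroma, endothelial, deacetylase, cholesterol and butyrate transport lists then gained 0.

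**Figure D3:**
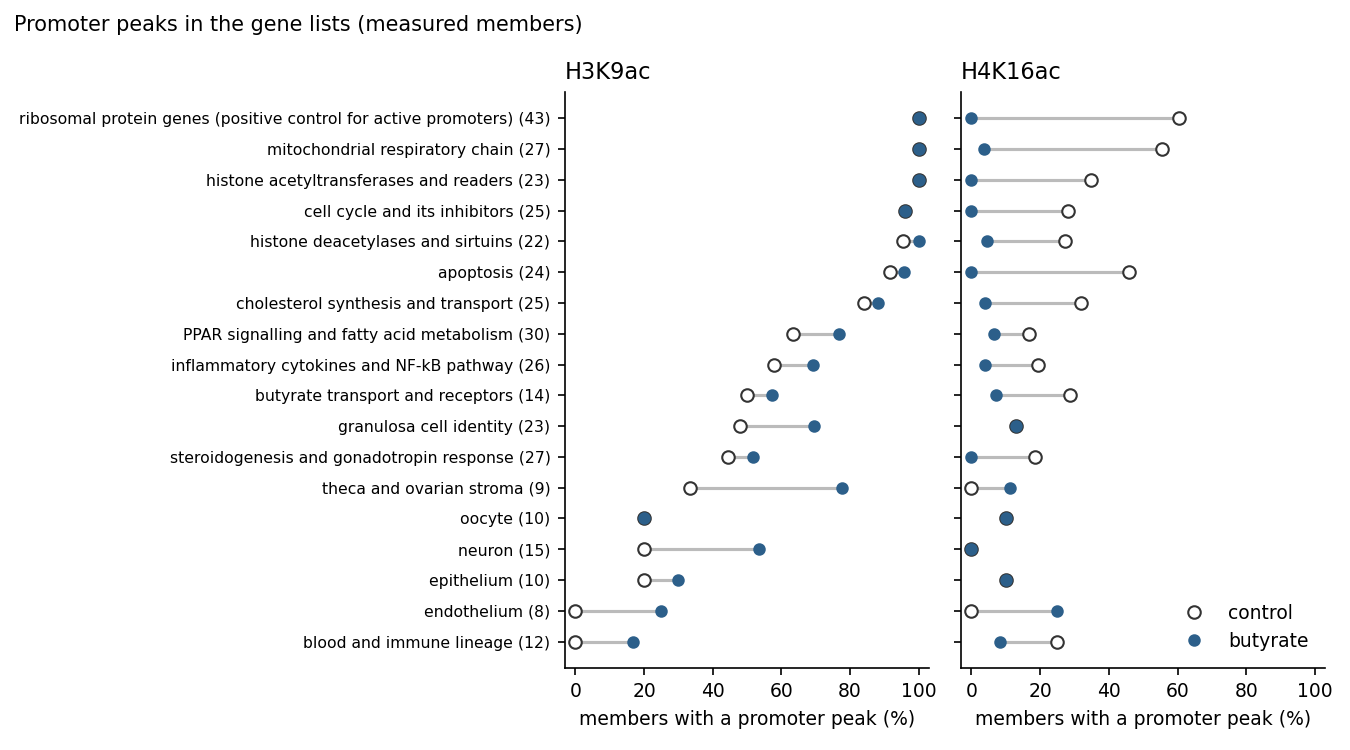
Measured members of each gene list with a promoter peak (%), for H3K9ac on the left and H4K16ac on the right, with open circles for control and filled circles for butyrate. The number of measured members is in parentheses. H3K9ac was at 3 genes in control and 7 of 9 with butyrate in the theca and stroma list and at 3 and 8 of 15 in the neuron list, and H4K16ac at 26 and 0 of 43 in the ribosomal list.

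Some anchor genes of the granulosa cell and of butyrate biology carried H3K9ac in both conditions, and others in neither. CYP11A1, the cholesterol side-chain cleavage enzyme, had a promoter peak at chromosome 15, 74365134 to 74366990, in control and at 74364401 to 74367971 with butyrate. FOXL2, the granulosa transcription factor, had one of 1985 bp on chromosome 3 in control and of 2576 bp with butyrate. INHA, the inhibin alpha subunit, had peaks of 942 and 2063 bp. PPARG, the fatty acid receptor, had peaks of 519 and 968 bp, and the cell cycle inhibitor CDKN1A peaks of 2402 and 3637 bp. CCND1, HDAC1 and KAT8 also kept a peak. PPARGC1A had no control peak within 1 kb of either of its starts. Its strongest butyrate promoter peak was at chromosome 4, 24472607 to 24473370. That peak lay at the RefSeq start (24472905) and far from the authors' start (23890077). The number of peaks inside the gene was 8 in control and 19 with butyrate. STAR, CYP19A1, HSD3B2, FSHR, NR5A1 and CD36 had no H3K9ac promoter peak in either library.

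The strongest promoter peaks among 1030 genes with H3K9ac in butyrate and none within 10 kb in control were at TRABD2B, LGALS9C, ZBTB18, APOBEC3C and BMAL2. TRABD2B, a metalloprotease that acts on Wnt proteins, had its peak at chromosome 1, 47996942 to 47997993, with a −log10 q of 23.4. ZBTB18 encodes a transcriptional repressor, and BMAL2 a partner of CLOCK in the circadian system. LGALS9C and APOBEC3C belong to families with near-identical copies, so their reads could come from a relative. The opposite list had 18 genes, led by CENPU, a centromere protein, the DNA glycosylase NEIL3, NXF3, TP53INP1 and ZNF724. CENPU had a control peak at chromosome 4, 184733634 to 184734380, with a −log10 q of 9.87. The strongest H3K9ac promoter peaks overall were at POLR2J3, RRM1, CENPP, NOL8 and DESI1 in control and at DNAJC21, ZFR, HDAC6, YAP1 and ATPSCKMT with butyrate. POLR2J3 also has near-identical copies.

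The libraries labelled H4K16ac had fewer peaks with butyrate. Ribosomal protein genes, respiratory chain genes and apoptosis genes, many of which had an H4K16ac promoter peak in control, had almost none with butyrate. Such losses were general, since 89.1% of all genes with a control promoter peak lost it. The list held 73586 peaks in control and 33752 with butyrate, 0.459 times as many, covering 30.7 and 11.9 Mb. At a q of 0.05 or less, 29141 and 381 peaks remained. The positions were mostly different too. Only 6.15% of control peaks (5.98 to 6.33) overlapped a butyrate peak, against 1.03% under random placement, so that 69057 peaks were lost and 29219 gained.

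H4K16ac promoter peaks were present at 3658 genes in control and at 896 with butyrate. They were kept at 400 genes, gained at 496 and lost at 3258. Independent lists over all 19239 genes would share 170.4, a number lowered by the 3459 genes without a histone peak near either end. The lost genes were 89.1% of those marked in control. With equal numbers of top peaks from the 2 lists, 640 genes gained and 2000 lost a peak, and with a 2.5 kb promoter window 1240 and 4037. Few butyrate peaks were individually strong. At a q of 0.05 or less, 4 genes gained a promoter peak and 2042 lost one. The largest q of 0.621 in the butyrate list means that a large part of that list can be background by the authors' own estimate. The control list reached a q of 0.304, and 39.6% of its peaks had a q of 0.05 or less. Part of the lost peaks can therefore be background too.

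Among the pathway lists, 26 of 43 ribosomal protein genes had an H4K16ac promoter peak in control and 0 with butyrate. RPL37, RPS18 and RPS25 had the strongest of these lost peaks. Of 27 respiratory chain genes, 15 lost the peak, led by NRF1, a regulator of mitochondrial genes, SDHC and UQCRC1, and NDUFS3 gained one. All 11 apoptosis genes with a control peak lost it, among them BIRC2, BAK1 and CASP8. The same held for 8 of 23 acetyltransferase and reader genes, led by BRD2, a reader of acetylated histones, NCOA3 and MSL1, a subunit of the KAT8 complex. Of all genes with a control peak 89.1% lost it, and among random lists of such genes, chosen after seeing the data, these lost counts lay at percentiles of 99.01 (ribosomal), 91.7 (respiratory chain), 84.7 (apoptosis) and 73.7 (acetyltransferases). At a q of 0.05 or less in both lists, 18, 6, 5 and 6 of their members lost a peak.

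The other pathway lists had fewer H4K16ac losses in number. The cell cycle list lost 7 genes, with CDKN1B, CDK2 and CCND1 the strongest, and the cholesterol list also lost 7, led by SCAP, FDPS and INSIG1. Deacetylases and sirtuins lost 6, led by HDAC7, HDAC6 and SIRT7, and gained HDAC1. Steroidogenesis lost all 5 of its marked genes, which were ADCY9, CYP11A1, HSD17B1, FDXR and SCARB1. Losses in the PPAR list included CPT2, FASN and ACADM, and PPARA was gained, the inflammatory list lost IL6, IL1R1, CXCL2 and IL1A, and the butyrate transport list lost SLC16A3, SLC16A1, ACADS and BSG and gained ACSS2. Granulosa identity lost ESR2 and INHA and gained RUNX1 and NR4A1. Among random lists of marked genes the lost counts lay at percentiles of 79.8 (cell cycle), 79.0 (deacetylases), 72.6 (steroidogenesis), 70.5 (butyrate transport), 51.3 (cholesterol), 38.3 (inflammatory), 31.6 (PPAR) and 25.9 (granulosa identity). At a q of 0.05 or less in both lists, 3 cell cycle, 3 cholesterol, 2 PPAR, 2 inflammatory and 0 butyrate transport genes lost a peak. Marker lists of other cell types had few H4K16ac peaks. Endothelial markers went from 0 to 2 of 8 (CDH5 and PECAM1), theca and stroma from 0 to 1 of 9 (COL1A2) and blood and immune from 3 to 1 of 12 (SPI1 and CSF1R lost). Epithelial markers exchanged MUC1 for KRT14, oocyte markers stayed at 1 of 10 and neuron markers at 0 of 15. The gained H4K16ac peaks of list members were weak, with a −log10 q from 0.235 at PPARA to 0.912 at CDH5, and none has a q of 0.05 or less. Some lost control peaks were weak as well. Those at CSF1R, BSG and SPI1 had a −log10 q of 0.588, 0.836 and 1.06, which also fails a q of 0.05.

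Among 857 genes with a control H4K16ac promoter peak and no butyrate peak within 10 kb, the strongest were RFC4, a clamp loader subunit of DNA replication, RPL37, BRD2, MORF4L1, a chromodomain protein of acetyltransferase complexes, and DTYMK, thymidylate kinase. The RFC4 peak lay at chromosome 3, 186806654 to 186807014, with a −log10 q of 5.39. The BRD2 peak lay at chromosome 6, 32969268 to 32971395. All 5 promoters carried H3K9ac in both conditions. The gained group had 91 genes, led by NUTM2D, which has near-identical copies, KCNIP3, STRA6, the receptor for retinol-binding protein, HLA-DMA and ACTL7B. NUTM2D had a −log10 q of 1.54 and ACTL7B, the weakest of the 5, one of 0.994. The strongest H4K16ac promoter peaks overall were at HSPA1L, CFAP68, FDXACB1, IMPDH2 and S100A1 in control and at MRPL24, LENEP, MSMP, TMCO6 and TMEM63A with butyrate. Of the anchor genes, CYP11A1, INHA and CCND1 had an H4K16ac promoter peak in control alone and HDAC1 with butyrate alone.

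H4K16ac peaks lay mainly inside genes in both lists, as did the gained but not the control H3K9ac peaks. In control, 67.8% were in gene bodies and 5.70% (5.54 to 5.87) at promoters, where random placement gave 41.6% and 1.68%. With butyrate, 51.7% were in gene bodies, 2.76% (2.59 to 2.94) at promoters and 45.6% in intergenic sequence.

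Most genes with an H4K16ac promoter peak also had H3K9ac. In control, 3286 of 3658 did, where 2019 would if the marks were independent. With butyrate, it was 687 of 896 genes, against 575.1. Both expected numbers count all 19239 genes. These include 3459 genes kept for having no histone peak near either end, which lowers the expectation. The small excess with butyrate can therefore come from the choice of genes. Over all peaks, 5.60% (5.44 to 5.77) of control H4K16ac peaks overlapped an H3K9ac peak, 5.20 times the share under random placement. With butyrate, 11.9% (11.6 to 12.3) did, 3.37 times the random share, in a list of H3K9ac peaks that covered more of the genome. With equal numbers of top peaks in both lists the direction turned, with 8.42% in control and 5.57% with butyrate.

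The IgG libraries had 5 peaks in control and 2 with butyrate on the chromosomes analysed, and none lay at a promoter. Their largest q was 0.0159 in control and 0.00233 with butyrate. The H4K16ac lists reached a q of 0.304 and 0.621, so overlap with the IgG peaks cannot show how much of the histone lists is background. Of control H3K9ac peaks, 4 overlapped an IgG peak of control and 2 one of butyrate. No peak of the other 3 histone lists overlapped an IgG peak.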

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

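Tests of read number and threshold for H4K16ac and of the strength of lost H4K16ac peaks were chosen after the results they bear on were seen. The other tests in this part had their outcomes set out before they were run.

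Peak numbers differed between the conditions for both marks. The ratio of butyrate to control was 3.57 for H3K9ac and 0.459 for H4K16ac. With 1 library in each group neither ratio was tested, and the marks' lists differ in threshold and background. Peaks on contigs outside the chromosomes analysed numbered 17 for control H3K9ac, 42 for butyrate H3K9ac, 29 for control H4K16ac and 12 for butyrate H4K16ac, against 1 and 0 in the IgG lists.

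For the higher number of H3K9ac peaks with butyrate, the butyrate library was read 1.21 times as deeply. After thinning its reads to the control number and applying the control limit on p, 64294 peaks remained, 2.89 times the control number, and at the control limit without thinning the ratio was 3.24. Both values argue against depth or threshold as the whole cause. A more efficient immunoprecipitation of the same sites stays open, since 6.73% of the strongest 10% of butyrate peaks had no control peak, between the 5% that it would allow and the 15% set as evidence against it. Wider acetylation under deacetylase inhibition may equally account for it, and 1 library per condition leaves that hypothesis untested.

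For the lower number of H4K16ac peaks, fewer reads would need a ratio of implied reads under 1, and it was 1.37. A stricter limit would need a smaller largest p, and the ratio of butyrate to control was 1.00. A weaker immunoprecipitation of the same sites should keep the strongest peaks best. The strongest 10% of control peaks were overlapped in 10.0% of cases and the weakest 10% in 4.91%, a ratio of 2.04 that lies between the bounds of 1.5 and 3, so a failed library and a loss of the mark cannot be told apart. Loss of H4K16ac under butyrate could be biological, but the share of 1.13% of peaks at a q of 0.05 or less in the butyrate list leaves little signal to judge it.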

How the results depend on the processing

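The q limit of 0.05 in every list, the thinning of reads and the random lists limited by control peaks were chosen after seeing the data. All other settings were planned. In no setting did a ratio of peak numbers cross 1. Where a value moved, the cause was not tested beyond what the setting itself removes or adds. Removal of IgG peaks moved no value beyond its limits, but it only took the control H3K9ac list from 22215 to 22211 peaks and left the other histone lists unchanged. Of 144 counts of list members that gained H3K9ac or lost H4K16ac, taken over 18 lists and 4 settings, 83 stayed within 1.5 times the value as deposited and 61 did not (34 for H4K16ac and 27 for H3K9ac). The 83 include counts that could not move, since both H3K9ac lists already end at a q of 0.05. They also include counts that were 0 in both settings. The number that stayed therefore overstates how stable the list counts were.

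At a −log10 q of at least 5 there were 14629 control and 27340 butyrate H3K9ac peaks, a ratio of 1.87, with 93.9% of control peaks shared, 14382 gained, 190 genes losing a promoter peak, and promoter shares of 77.2% and 47.7%. H4K16ac had 60 control and 0 butyrate peaks, a ratio of 0, so 0% were shared, 0 genes gained and 19 lost a promoter peak, the promoter share was 25% in control, and 33.3% of control peaks overlapped H3K9ac. No share of butyrate peaks could be computed there.

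At a fold of at least 5, H3K9ac had 11018 and 13621 peaks, a ratio of 1.24, with 78.7% shared, 5393 gained, 1259 genes losing a promoter peak, and promoter shares of 82.9% and 67.5%. H4K16ac had 263 and 31 peaks, a ratio of 0.118, with 0% shared, 31 gained, 0 genes gaining and 57 losing a promoter peak, promoter shares of 18.3% and 0%, and 15.6% and 3.23% of peaks overlapping H3K9ac.

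With equal numbers of top peaks, 79.7% of control H3K9ac peaks were shared and 7743 gained, 626 genes gained and 510 lost a promoter peak, and the butyrate promoter share was 54.5%. For H4K16ac, 7.29% were shared, 2000 genes lost a promoter peak, the control promoter share was 6.94%, and 8.42% (control) and 5.57% (butyrate) overlapped H3K9ac.

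With merging within 1 kb, H3K9ac had 13996 and 47643 peaks, 94.2% shared, 35321 gained, and promoter shares of 68.0% and 23.9%. For H4K16ac, 7.20% were shared, the control promoter share was 6.00%, and 5.91% and 12.9% overlapped H3K9ac. With an overlap of 50% of the shorter peak, 89.0% of control H3K9ac and 4.01% of control H4K16ac peaks were shared, and 4.49% and 8.47% of H4K16ac peaks overlapped H3K9ac.

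With a 2.5 kb window, promoter shares were 73.2% and 30.9% for H3K9ac and 11.3% and 9.46% for H4K16ac, and 1240 genes gained an H4K16ac promoter peak. With the authors' gene columns, 888 genes lost H3K9ac, 327 gained H4K16ac and 2098 lost it.

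At a q of at most 0.05 in every list, H4K16ac had 29141 and 381 peaks, a ratio of 0.0131, with 0.192% shared, 326 gained, 4 genes gaining and 2042 losing a promoter peak, promoter shares of 7.19% and 2.36%, and 7.61% and 15.2% overlapping H3K9ac. With the butyrate H3K9ac reads thinned, 90.9% of control peaks were shared and the ratio was 2.89. The effect of depth was computed for the butyrate H3K9ac list alone. A summit in the H4K16ac lists rested on a median of 9 reads in control and 10 with butyrate, against 20 and 17 in the H3K9ac lists.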

Other observations

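The counts in the first 2 paragraphs and the tests of background reads in the last were chosen after the data were seen, the comparison over all 4 lists after that of control H3K9ac. The test of H3K9ac-marked genes in the last paragraph had its outcomes set out beforehand.

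The genes with the largest rise in H3K9ac peaks were chosen for that rise, and long genes have more room for peaks. GSE1 had 18 H3K9ac peaks in control and 110 with butyrate, the largest increase among genes with a known start. CUX1, a homeobox transcription factor, went from 7 to 81, CAMTA1, a calmodulin-binding transcription activator, from 7 to 72, and RAP1GAP2 from 7 to 70. PDE4D, a cyclic AMP phosphodiesterase, went from 13 to 67 and TNS3 from 1 to 46. The 15 genes with the largest increase were 118.4 to 1553 kb long. The number of H3K9ac peaks inside the gene was higher with butyrate at 9389 genes and lower at 832. At the 10583 genes with a promoter peak in both lists, the strongest one of each list was compared. It was wider with butyrate at 7777 genes and narrower at 2801. Its median width was 1197 bp in control and 1670 bp with butyrate. The compared peaks did not always overlap, as at RPL37 and HDAC6, so the widths do not follow single peaks. The butyrate list was read 1.21 times as deeply and held p up to 0.00108, against 0.000348 in control. These counts and widths were not repeated after thinning or with equal numbers of top peaks. How far they rest on depth, threshold and list length was therefore not tested.

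Gained H3K9ac peaks overlapped the H4K16ac peaks of both conditions more often than under random placement. Random placement does not keep peaks inside genes, where gained H3K9ac and H4K16ac peaks mainly lay, so shared location in genes was not separated. Of the gained H3K9ac peaks, 10.9% overlapped a control H4K16ac peak, against a mean of 2.73% and a maximum of 3.29% under random placement. The overlap with butyrate H4K16ac peaks was 5.19%, against 1.23% under random placement. Of H3K9ac butyrate peaks that were also in control, 22.1% overlapped a control H4K16ac peak and 4.53% a butyrate one, so the order of kept and gained peaks differed between the 2 H4K16ac lists. The kept peaks were wider, with a median of 1279 bp against 404 bp for the gained ones. No random share was computed for the kept peaks, so this order cannot be interpreted.

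H4K16ac promoter peaks were rare on chromosomes 4, 13 and 14 of control cells, at 3.07%, 5.61% and 7.88% of genes, against 11.3% to 26.3% on the other 20 chromosomes. Inactive genes would explain this only if H3K9ac-marked genes there carried H4K16ac as often as elsewhere. Those genes did so in 6.59%, 9.25% and 12.5% of cases, and the highest of these minus the lowest other chromosome (21.4%) gave a difference of -8.92 percentage points, which argues against it. Fewer background reads were looked at as another explanation. On chromosomes 4 and 14 the shares of summits at the background floor exceeded those of all 20 other chromosomes in each histone list. The excess was 19.7 percentage points in control H4K16ac and at least 1.22 in every list. Their control H3K9ac promoter peaks, at 46.7% and 60.4% of genes, lay within the 40.9% to 61.5% of the others. A lower background alone makes a peak easier to call at a given pileup, and immunoprecipitated reads per chromosome were not computed. These shares therefore cannot decide what made H4K16ac promoter peaks rare there. For chromosome 13 even a lower background stays open, since the lists disagreed. Its share lay 7.95 percentage points above the highest other in control H3K9ac (25.8% against 17.8%). The difference was -8.76 in control H4K16ac (15.8% against 24.6%), -6.00 for butyrate H3K9ac and -18.4 for butyrate H4K16ac. With butyrate, H3K9ac also differed on these chromosomes. Its peaks went from 621 to 1138 on chromosome 4, 376 to 821 on chromosome 13 and 681 to 1401 on chromosome 14. In proportion, each rise was smaller than on any of the other 20 chromosomes.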
